A study of Mus musculus with 316 samples.

How the data were processed

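The data were 1 table of the whole series, with 22073 rows and 316 cells. It held 92 ERCC spike-in rows, 11 reporter and selection cassette rows, and 21970 mouse gene rows. The library molecule was polyA RNA, per the labels. HISAT 0.1.6, Salmon 0.3.2 and the GRCm38 build are named in the submitters' processing notes, without the role of each. The annotation, the cell isolation, the sort gate and the library kit are not given in the sources used here. The values deposited by the authors are on a natural log scale. The base was read from the values: exp(x) - 1 gave totals between 414503 and 962583 per cell, with similar group means, as TPM with some rows left out would. The labels do not state the base or the added constant.

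The deposited natural log values were turned back to TPM and then to log2(TPM + 1), with a pseudocount of 1. Differences on this scale understate low genes. TPM keeps no sequencing depth, so intervals on reads could not be given and the depth per cell is unknown. An exact 0 is given as listed at 0, since widely used genes were also at 0 in some cells. A gene was called detected at a TPM of 1 or more.

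Cells were grouped by their titles. Cells of a group with log2 profiles that correlated above a Pearson r of 0.9 were averaged and counted once, since they may be 1 library deposited more than once. This joined ESC cells 22 and 64 (r = 0.942), Eng_ES-HSC cells 31 and 34 (r = 0.989) and Eng_ES-HSC cells 33 and 36 (r = 0.973), while the highest r of any other pair was 0.841. Of the 313 cells left, 261 with at least 1000 genes were kept. That filter left out 26 of 47 Eng_ES-HSC, 19 Eng_BM-HSC, 7 FL_HSC and 0 ESC cells. Doublets were not called, since no UMI counts were used here. Cells were not clustered, and the group labels were used as they stand.

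Each cell is a sample in the series, and the labels name no animal or culture, so a group was treated as 1 sample. No test, p-value, standard error or count of changed genes was computed. The 6 pairwise comparisons used differences of mean log2(TPM + 1) over the 13239 genes with a mean TPM of at least 1 in some group. The 36 gene lists were fixed before the data were examined. For each list the median difference of its measured members was placed among 10000 random lists matched on expression in 20 bins, and members that differed by at least 1 were counted. Xist and the genes H19 and Ighm were not analysed here. Shares of cells have exact Clopper-Pearson 95% intervals, and the limit for a share of 0 is 3 cells of the total. Both cover counting error only.

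The named genes followed a rule also fixed before the data were examined. It took the 10 largest differences in each direction in the 3 comparisons between HSC groups, for Eng_ES-HSC against both other HSC groups, and for ESC against all 3 HSC groups. The higher group had to have a mean TPM of at least 10 and detection in at least 50% of cells. Predicted, mitochondrial, ribosomal protein and small RNA genes were skipped, and members of the fixed lists could be named with any value. Of the mouse gene rows, 21067 had a symbol in GENCODE M21, from which coordinates were taken.

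The steps were tested on simulated data, by splitting the cells of 1 group at random and multiplying 100 genes by 4 and 100 by 0.25. Changed genes and unchanged lists were drawn only from well detected genes. These passed, in the group that was split, the mean TPM and detection minima set above for named genes. Genes below those minima were not tried, so the shares do not cover lists that hold many of them. Over 13239 genes with 21 against 55 Eng_BM-HSC cells, 85% of the raised and 99% of the lowered genes had the right sign. With FL_HSC cells the shares were 92% and 100%. Lists of 15 unchanged genes fell outside the central 95% of random lists in 4% and 2.5% of 200 draws. Both parts of each split came from 1 group, so they were drawn from cells with the same range of gene numbers. The compared groups differed in gene number. The shares from simulated data therefore do not show how often unchanged lists fall outside the range in those comparisons.

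There were 12 alternatives fixed in advance for group values: other pseudocounts, filters on genes and cells, log2 of mean TPM, trimmed means, quantile normalization, leaving out mitochondrial, ribosomal and globin genes, and odd- or even-numbered cells. Other detection thresholds were tried for shares of cells, and 49 drawn reference cells for the nearest profile. After seeing the data 4 more were added: leaving out cells over 50% mitochondrial, only cells with 1000 to 3000 genes, near-identical cells counted separately, and Eng_BM-HSC cells matched on gene number. A list median, all-gene median or correlation counted as moved when it shifted by at least the SD over cells of the same quantity. That tolerance replaced a fixed one after first results had been seen. A gene difference counted as moved when it changed by a factor of more than 1.5. A share of cells counted as moved when it left the exact interval of its main value. List and all-gene medians under 0.5 in size were not counted as changing sign. The test of a common pool used 100 random splits of the lists and 1000 bootstrap draws of cells. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.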

Results

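Single-cell RNA sequencing had been done on 4 kinds of mouse cell. Embryonic stem cells (ESC) are pluripotent cells grown in culture, and 78 of them were deposited. Haematopoietic stem cells (HSC) are the blood-forming cells that rebuild the blood after transplantation. They were represented by 94 cells from fetal liver (FL_HSC), 95 bone marrow-derived cells taken after engraftment (Eng_BM-HSC), and 49 cells that had been derived from ESC and had then engrafted (Eng_ES-HSC). The series title names Notch activation and lymphoid potential in ESC-derived HSC, so the comparisons asked how near the engrafted ESC-derived cells lay to the reference HSC and to ESC. Values were TPM, a transcript abundance corrected for transcript length, and differences are given between group means of log2(TPM + 1) over cells.

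The groups differed in how many genes were detected. Among all cells, the median number of genes at a TPM of 1 or more was 5433 in ESC, 4151 in FL_HSC, 2407 in Eng_BM-HSC and 973 in Eng_ES-HSC. Cells with fewer than 1000 genes were left out, which kept 77 ESC, 87 FL_HSC, 76 Eng_BM-HSC and 21 Eng_ES-HSC cells. The kept cells had medians of 5433, 4233, 2585 and 1609 genes, in the same order. Mitochondrial transcripts made up a median of 19.8% of the TPM in ESC, 9.31% in FL_HSC, 13.4% in Eng_BM-HSC and 20% in Eng_ES-HSC. The number of reads per cell is unknown, since TPM keeps no depth.

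**Figure D1:**
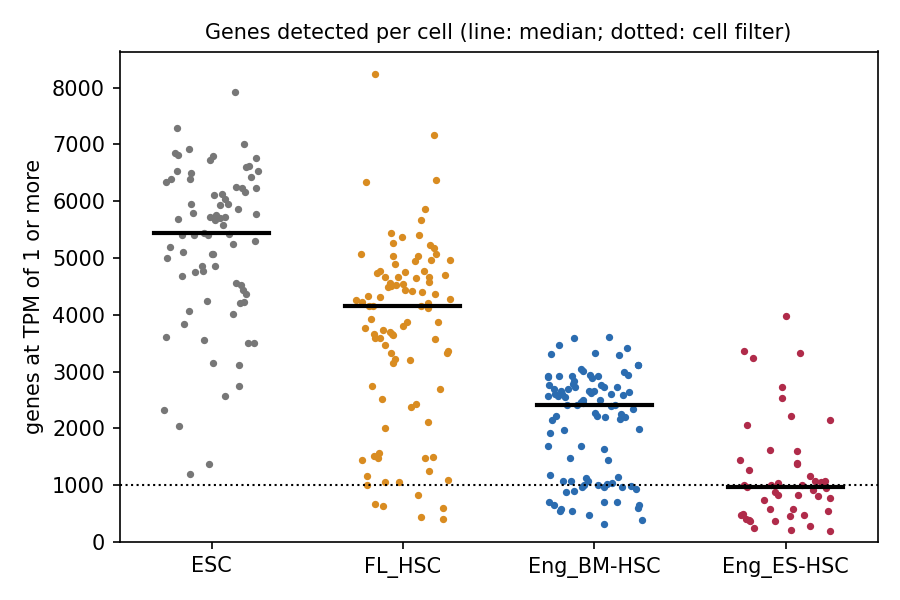
Genes detected at a TPM of 1 or more (y axis, number of genes) in each cell, by group (x axis); each point is 1 cell, horizontal bars are medians and the dotted line is the filter at 1000 genes. The Eng_ES-HSC median of 973 lies below the filter, while the ESC median is 5433.

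Each deposited sample was 1 cell, and the labels named no animal or culture, so each group counts as 1 sample. No test between groups was therefore possible, there is no replicate error, and each group had its own library identifier, so group and library cannot be told apart. Intervals on shares of cells are exact 95% binomial intervals and cover the counting of cells only. For a gene detected in 0 cells, the count of cells allows detection in up to 3.90% of ESC, 3.45% of FL_HSC, 3.95% of Eng_BM-HSC and 14.3% of Eng_ES-HSC cells, and it sets no limit on transcripts that were present but missed. Percentiles of gene lists are positions among 10000 random lists of the same size and expression, and describe these libraries only.

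The mean profile of the engrafted ESC-derived cells lay nearest to that of the engrafted marrow cells. Across 13239 genes, Spearman's rho of Eng_ES-HSC was 0.717 with Eng_BM-HSC, 0.617 with FL_HSC and 0.543 with ESC. Eng_BM-HSC and FL_HSC had the highest rho, 0.788. In cells with 1000 to 3000 genes the order of FL_HSC and ESC turned, with rho of Eng_ES-HSC at 0.402 and 0.418. FL_HSC with ESC gave 0.666 and Eng_BM-HSC with ESC gave 0.611. Genes are not independent replicates, so these values rank profiles and carry no error. Taken cell by cell, 21 of 21 Eng_ES-HSC cells correlated best with the Eng_BM-HSC mean (100%, exact interval 83.9% to 100%), with a median rho of 0.350, against 0.249 for FL_HSC and 0.254 for ESC. Eng_BM-HSC was also the reference whose gene number per cell lay nearest to theirs.

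On average, the engrafted ESC-derived cells carried far more neutrophil transcripts than the engrafted marrow cells. The ESC-derived cells carried far fewer transcripts of stem-cell regulators. S100a8 and S100a9, which encode the subunits of calprotectin in neutrophils and monocytes, led the genes higher in Eng_ES-HSC than in Eng_BM-HSC. S100a8 (chromosome 3, 90668978 to 90670035, GRCm38) had a mean TPM of 23514 against 15.9, and was detected in 81% (58.1% to 94.6%) against 2.63% (0.320% to 9.19%) of cells. At the other end stood Ifitm1, an interferon-inducible membrane protein, with a difference of -6.47 and detection in 9.52% against 86.8% of cells. Lmo2 and Angpt1, a bridging factor of the stem-cell transcription complex and a niche ligand of the Tie2 receptor, each differed by -5.22.

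Other genes named by size as higher in Eng_ES-HSC than in Eng_BM-HSC included Cd52 (4.76), Lgals1 (4.33), Id2 (3.64), Tmsb4x (3.18), Ngp (2.80), Cks2 (2.73) and Cxcr4 (2.69). Cd52 is a lymphocyte and myeloid surface antigen, Id2 an inhibitor of basic helix-loop-helix factors, Ngp a neutrophil granule protein and Cxcr4 the chemokine receptor that holds cells in marrow. On the lower side were Adgrg1 (-5.79), an adhesion receptor of HSC, Ctla2b (-5.68), Stmn1 (-5.60), Tmem176b (-5.44), Car2 (-5.43), Cnbp (-5.42) and Impact (-5.25). Car2 was detected in 47.6% of Eng_ES-HSC and 100% of Eng_BM-HSC cells.

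Of the 29 measured genes of the HSC identity list, 14 were lower by at least 1 log2 unit in Eng_ES-HSC than in Eng_BM-HSC and 0 were higher. The list median was -0.99, at the 0th percentile, where random lists had a median of -0.19. Its size depended on the processing: -0.70 with matched gene number, -1.85 at a pseudocount of 0.1 and -4.21 with log2 of the mean TPM. Housekeeping genes were lower too, with a median of -1.64 at the 0.36th percentile and 8 of 12 lower, but with Eng_BM-HSC cells matched on gene number their median was -0.37 at the 6.42nd percentile, inside the central 95% of random lists. Cd34, a sialomucin of stem and progenitor cells, was detected in 4.76% (0.120% to 23.8%) of Eng_ES-HSC and 68.4% (56.7% to 78.6%) of Eng_BM-HSC cells. Hlf, a transcription factor of primitive HSC, was detected in 9.52% (1.17% to 30.4%) against 67.1% (55.4% to 77.5%). Meis1 and Erg, both HSC transcription factors, were listed at 0 in all 21 Eng_ES-HSC cells and were detected in 36.8% and 39.5% of Eng_BM-HSC cells. Slamf1, seen in few cells of either group, differed by 0.03, and Runx1 by -0.64, which turned to 0.81 with matched gene number. At least 3 list members were found in 42.9% of Eng_ES-HSC and 100% of Eng_BM-HSC cells, and also in 85.7% of ESC, whose cells hold more detected genes.

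Markers of mature blood cells stood beside these differences. They were unevenly spread over the 21 Eng_ES-HSC cells. As mean log2(TPM + 1) over a list, granulocyte scores ran from 0.108 to 8.91, with quartiles of 0.696 and 4.64. T and NK cell scores ran from 0 to 4.51, erythroid scores from 0 to 4.53, and monocyte and macrophage scores from 0 to 6.08. Group values therefore do not describe each cell. Of 14 measured granulocyte genes, 10 were higher in Eng_ES-HSC than in Eng_BM-HSC by at least 1 and 1 was lower, with a median of 2.24 at the 100th percentile. Elane and Ctsg, the primary granule proteases neutrophil elastase and cathepsin G, were each detected in 33.3% of Eng_ES-HSC cells and were listed at 0 in every Eng_BM-HSC cell. Camp had a mean TPM of 5434 against 15.8. Adult alpha globin Hba-a2 was detected in 47.6% (25.7% to 70.2%) against 1.32% of cells. The T-cell receptor component Cd3e was detected in 33.3% (14.6% to 57%) against 0%, and the kinase Lck in 42.9% against 5.26%. The list medians were 0.53 for T and NK cell genes, 0.79 for monocyte and macrophage genes, 0.24 for erythroid genes and 0.51 for mast cell and basophil genes, each at or above the 99.96th percentile. With Eng_BM-HSC cells matched on gene number, the erythroid median stayed at 0.24 but lay at the 96.1st percentile, inside the central 95% of random lists. The mast cell and basophil genes rested on few cells, since Fcer1a, Gzmb, Mcpt8 and Tpsb2 each came from 1 cell.

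The early lymphoid and Notch lists lay inside the range of random lists between the engrafted groups. Early lymphoid genes had a median of -0.19 at the 42.1st percentile, with 2 of 16 higher and 4 lower by at least 1. Cd52 and Il7r, the interleukin-7 receptor, were the higher members, and Il7r was detected in 28.6% (11.3% to 52.2%) against 5.26% of cells. Flt3, a cytokine receptor of lymphoid-primed progenitors, differed by -2.42, and Dntt, the DNA polymerase that adds bases at antigen receptor joints, differed by -1.04. Notch pathway genes had a median of -0.12 at the 31st percentile, with 0 of 18 higher and 4 lower. Notch2 differed by -1.31, and Notch1 was detected in 4.76% against 9.21% of cells. Among genes with a mean TPM of 10 or more, the Notch median was -0.68, and with log2 of the mean TPM the early lymphoid median was -1.44.

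Class II antigen presentation genes separated the engrafted groups further. Of 8 such genes, 6 were lower by at least 1 in Eng_ES-HSC than in Eng_BM-HSC, with a median of -1.53 at the 0.03rd percentile. H2-Aa was detected in 53.9% (42.1% to 65.5%) of Eng_BM-HSC cells and in 1 of 21 Eng_ES-HSC cells, and that cell alone gave the Eng_ES-HSC mean TPM of 531. Genes of the S phase and of G2 and M phase had small medians of 0.22 and 0.41, at the 99.85th and 100th percentiles. Mki67, a marker of cycling cells, was detected in 47.6% (25.7% to 70.2%) of Eng_ES-HSC and 14.5% (7.45% to 24.4%) of Eng_BM-HSC cells. Set against Eng_BM-HSC cells of matched gene number, the HSC identity median was -0.70, the granulocyte median 1.93 and the class II median -0.84, with 3 of 8 class II genes lower by at least 1. The S phase median was then 0.37 at the 97.1st percentile, inside the central 95% of random lists, and the G2 and M phase median 0.39 at the 99.2nd percentile, above it. Oxidative phosphorylation genes turned from -0.57 to 0.60 under that matching.

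**Figure D2:**
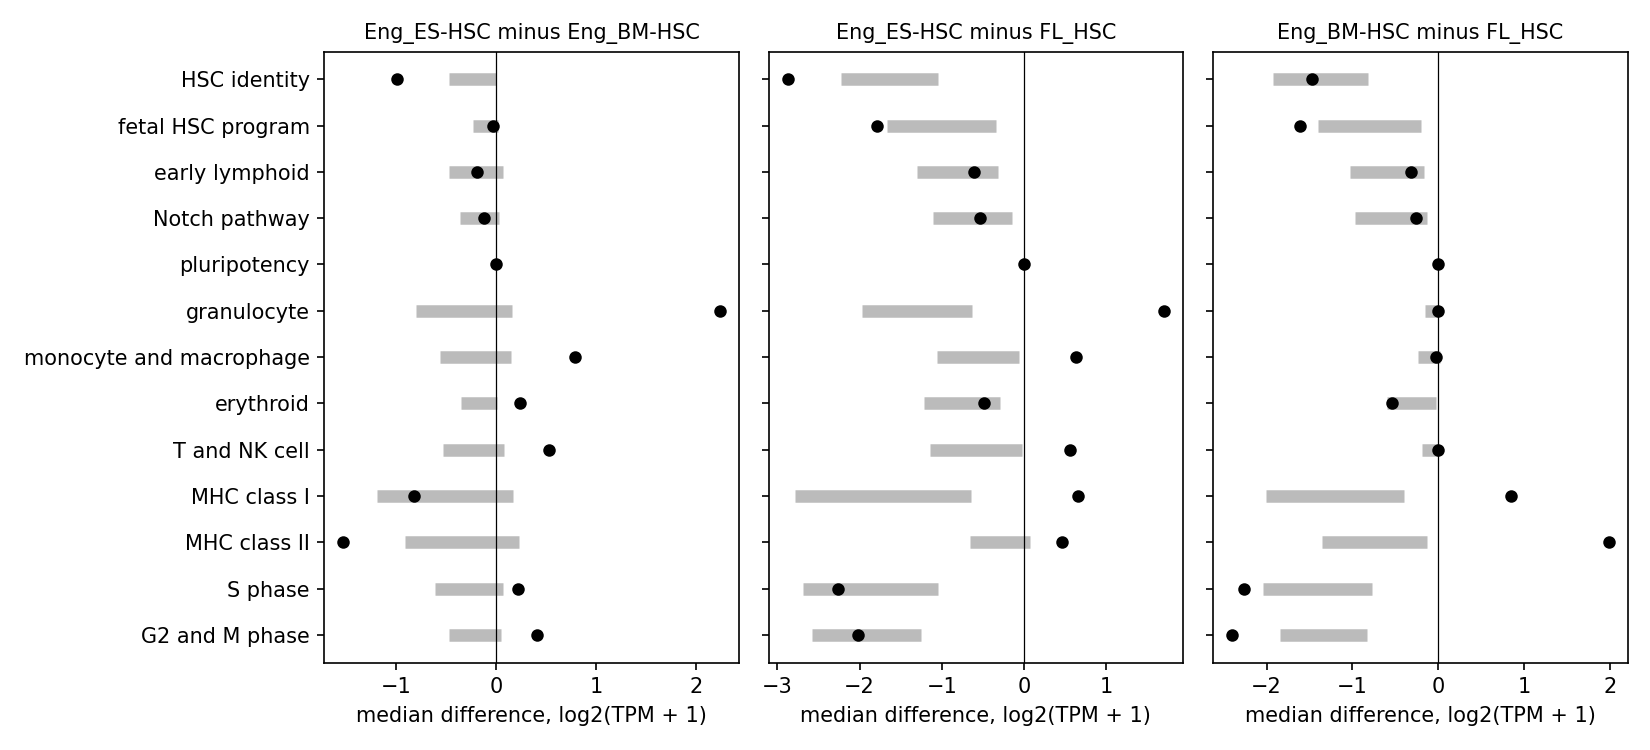
Median difference of each gene list in log2(TPM + 1) units (x axis, black points) for 3 comparisons of HSC groups, with the central 95% of matched random lists as grey bars. In Eng_ES-HSC minus Eng_BM-HSC, HSC identity (-0.99) lies left of its bar and granulocyte genes (2.24) right of it.

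Against fetal liver HSC, the engrafted ESC-derived cells lacked much of the fetal programme and again carried granulocyte transcripts. Hmga2, a chromatin protein of fetal HSC, was detected in 9.52% (1.17% to 30.4%) of Eng_ES-HSC and 95.4% (88.6% to 98.7%) of FL_HSC cells, a difference of -6.01. Of 12 measured fetal HSC genes, 10 were lower by at least 1 and 0 were higher, with a median of -1.79 at the 0.96th percentile. Lin28b, a repressor of let-7 microRNAs, was found in 0 of 21 Eng_ES-HSC and 32.2% of FL_HSC cells. S100a8 and S100a9 were listed at 0 in all 87 FL_HSC cells.

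By size, the other genes higher in Eng_ES-HSC than in FL_HSC were Cd52 (5.26), Plac8 (3.73), 9930111J21Rik2 (3.33), H2-K1 (3.31), Id2 (3.30), Fam73a (3.24), Ngp and Ctf2 (2.81). H2-K1 is a classical class I antigen presentation gene. Those lower were Psmc4 (-7.95), Eef1g (-7.63), Mdh2 (-7.35), Cnbp (-7.33), Ruvbl1 (-7.21), Stmn1 (-7.11), Atp5b (-7.10), Cct5 (-6.87), Paics (-6.80) and Sfr1 (-6.67). The median over all 13239 genes was itself -0.52.

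HSC identity genes had a median of -2.88 in Eng_ES-HSC minus FL_HSC, at the 0th percentile, with 25 of 29 lower and 1, Ly6a (1.40), higher. The granulocyte median was 1.70, with 9 of 14 higher and 0 lower, and class I genes had a median of 0.66, with 6 of 12 higher and 1 lower, both at the 100th percentile. Early lymphoid genes (-0.61, 75.3rd percentile) and Notch genes (-0.53, 62.5th percentile) lay inside the range of random lists. Hoxa cluster genes had a median of -0.59 at the 1.17th percentile, and Hoxa9, a regulator of HSC self-renewal, was found at a TPM of 1 or more in 40.2% of FL_HSC and 0% of Eng_ES-HSC cells. The Hoxb cluster median was -0.030. Without a filter on cells the class I median turned to -0.15. When only cells with 1000 to 3000 genes were compared, the HSC identity median was -1.06 and the fetal median -0.80, and the Notch median turned to 0.057.

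The pair of reference HSC groups separated by antigen presentation and fetal genes, and by the globin gene Hbb-bt. H2-K1 led the genes higher in Eng_BM-HSC than in FL_HSC, with a mean TPM of 833 against 73.8 and a difference of 4.45. Hbb-bt, an adult beta globin, led the genes lower in Eng_BM-HSC, at -6.49, and was detected in 10.5% (4.66% to 19.7%) against 85.1% (75.8% to 91.8%) of cells. Hmga2 differed by -5.54. H2-Aa was detected in 53.9% of Eng_BM-HSC cells and was listed at 0 in every FL_HSC cell.

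Also higher in Eng_BM-HSC were PISD (4.25), H2-Q6 (4.20), H2-Q7 (3.55), Fos (3.34), 9930111J21Rik2 (3.31), Nkg7 (3.18), Mmachc (3.09) and Glipr1 (2.91). H2-K1, H2-Q6 and H2-Q7 are related genes, so reads of shared sequence can be split between them. Also lower were Lgals1 (-6.44), Ruvbl1 (-6.00), Psmc4 (-5.68), Eno1 (-5.66), Oser1 (-5.39), Cpsf3l (-5.33), Tuba1c (-5.28) and Copz1 (-5.18).

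Among lists, class II genes had a median of 1.98 with 6 of 8 higher, class I genes 0.84 with 5 of 12 higher, and interferon response genes 0.42 with 4 of 19 higher, all at the 100th percentile in Eng_BM-HSC minus FL_HSC. Ifi44 and Rtp4, both interferon-induced, were 2.01 and 1.98 higher. The fetal HSC median was -1.61 at the 0.40th percentile, with 10 of 12 lower. S phase genes (-2.26, 18 of 20 lower) and G2 and M phase genes (-2.40, 19 of 20 lower) lay at or below the 0.57th percentile, as did glycolysis (-3.36) and oxidative phosphorylation (-2.68). HSC identity genes had a median of -1.48, which was at the 38.3rd percentile, so they stood no lower than other genes of their level. In cells with 1000 to 3000 genes the HSC identity median was -0.064, the fetal median -0.53 and the oxidative phosphorylation median turned to 0.23.

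**Figure D3:**
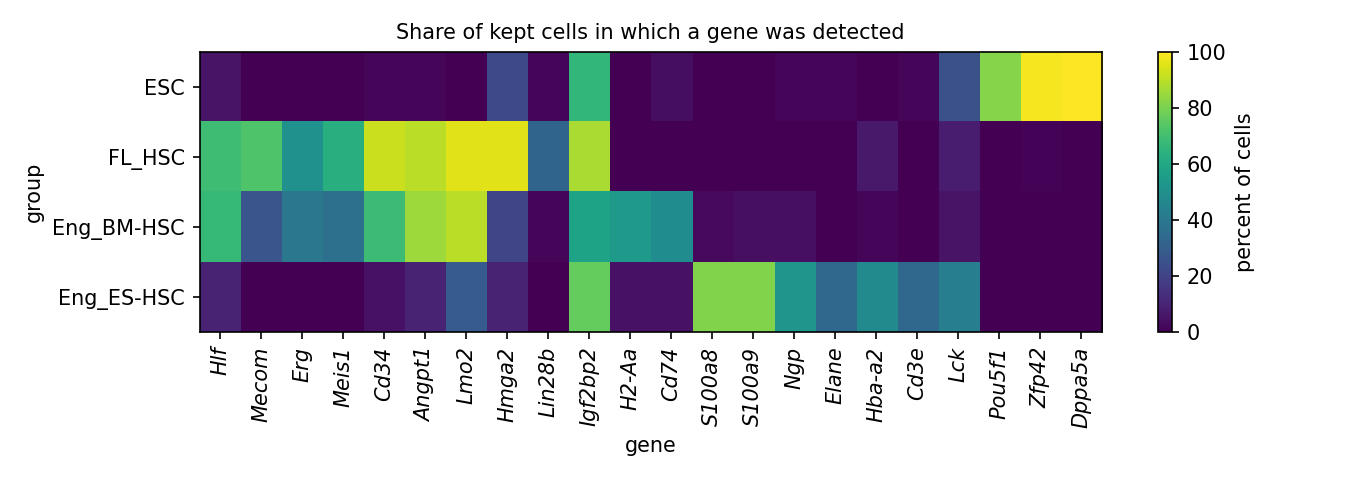
Share of kept cells (colour, percent) in which each gene (x axis) was detected at a TPM of 1 or more, in each group (y axis). S100a8 reached 81% in Eng_ES-HSC against 2.63% in Eng_BM-HSC, while Cd34 reached 4.76% against 68.4%.

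Embryonic stem cells carried the pluripotency programme, and none of the HSC groups carried it as a whole. Dppa5a, a pluripotency-associated RNA-binding protein, had a mean TPM of 5849 and was detected in 100% (95.3% to 100%) of ESC, and it was listed at 0 in every HSC. Pou5f1, the core pluripotency factor, was detected in 81.8% (71.4% to 89.7%) of ESC and in 0 of 21 Eng_ES-HSC cells. The pluripotency list median relative to ESC was -4.27 in Eng_ES-HSC, -4.24 in FL_HSC and -4.21 in Eng_BM-HSC, each at the 0th percentile with 23 of 24 members lower by at least 1. In cells with 1000 to 3000 genes, of which only 6 were ESC, these medians were -1.60, -1.64 and -1.59. Nanog was listed at a TPM of 1 or more in 39.1% of FL_HSC, 60.5% of Eng_BM-HSC and 42.9% of Eng_ES-HSC cells too, with mean TPM of 2.83, 6.20 and 8.64 against 505 in ESC.

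The genes named as highest in ESC were Dppa5a, Fabp3, Spp1, Ckb, Dppa3, Gsta4, Trap1a, Mt2, Zfp42 and Calcoco2. Fabp3, Dppa3 and Trap1a were listed at 0 in every HSC. Zfp42, a marker of naive pluripotency, had a mean TPM of 444 in ESC. Mt2 had a mean TPM of 903 in ESC but 1247 in Eng_ES-HSC, where 14.3% of cells carried it, so its order between those groups turned when TPM were averaged before taking logs. The genes named as lowest in ESC were Arhgdib, B2m, Srgn, Cd47, H2-D1, Fli1, Emp3, Alox5ap, Gmfg and Coro1a. B2m, the class I light chain, differed by 8.94 between Eng_ES-HSC and ESC, and Fli1, a blood and endothelial transcription factor, by 4.29. Coro1a, an actin regulator of leukocytes, was listed at 0 in every ESC.

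HSC identity genes separated fetal and marrow HSC from ESC more than they separated the ESC-derived cells. Their median relative to ESC was 2.79 in FL_HSC, with 23 of 29 higher and 1 lower, and 1.0 in Eng_BM-HSC, with 15 higher and 2 lower. In Eng_ES-HSC it was 0, which lay at the 99.97th percentile because random lists of that level were lower than in ESC, with 2 members, Runx1 (1.72) and Lmo2 (1.5), higher and 5 lower. Early lymphoid medians were 0.32, 0.38 and 0.028 in FL_HSC, Eng_BM-HSC and Eng_ES-HSC, at the 99.3rd, 100th and 99.99th percentiles, Notch medians 0.020, -0.26 and -0.39, and Hoxa medians 0.54, 0.11 and 0. The fetal HSC median was 1.06 in FL_HSC, -0.90 in Eng_BM-HSC and -0.90 in Eng_ES-HSC. Only 6 ESC had 1000 to 3000 genes. In that range the fetal median turned to 0.38 in Eng_BM-HSC and was 0 in Eng_ES-HSC. The Notch medians were then 0.59 in Eng_BM-HSC and 0.26 in Eng_ES-HSC.

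The genes that set Eng_ES-HSC apart from both reference HSC groups repeated the contrasts above. Besides S100a8, S100a9, Cd52, Id2, Ngp and Cxcr4, the higher genes were Fam73a, Ebf1, Tmsb10 and Psap. Ebf1, a B-cell lineage factor, was detected in all 21 Eng_ES-HSC cells, with a difference of 2.31 from Eng_BM-HSC and 1.87 from FL_HSC, and also in 92.2% of ESC. Other B-cell genes did not go with it: Cd79a was listed at 0 in every HSC and Pax5 was below a TPM of 1 in all Eng_ES-HSC cells. The lower genes were Ifitm1, Stmn1, Adgrg1, Car2, Cnbp, Tmem176b, Angpt1, St13, Lmo2 and Impact.

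**Figure D4:**
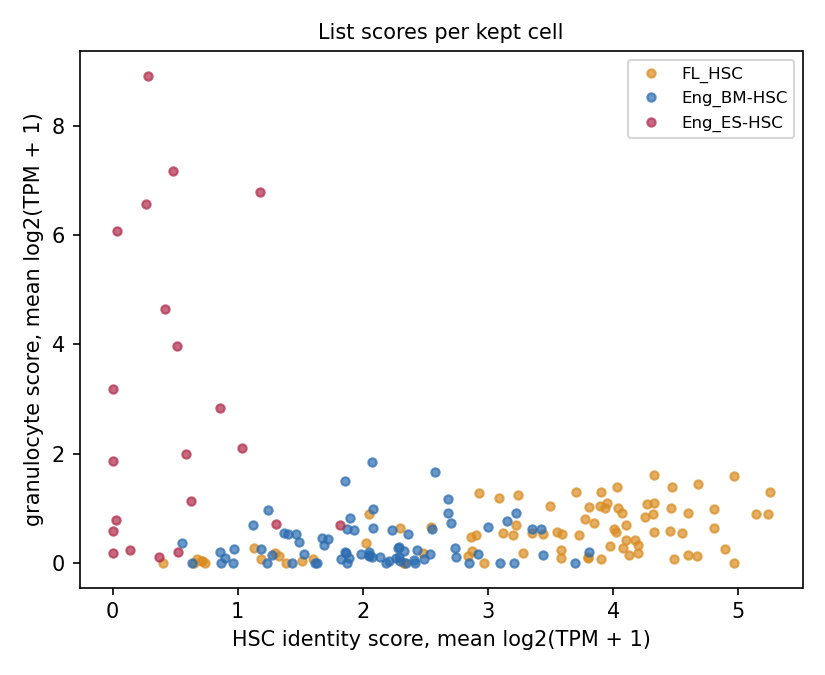
Granulocyte score against HSC identity score of each kept HSC (both axes, mean log2(TPM + 1) over the list), coloured by group; each point is 1 cell. Median granulocyte scores were 1.99 in Eng_ES-HSC, 0.204 in Eng_BM-HSC and 0.532 in FL_HSC, and median HSC identity scores 0.416, 2.08 and 3.80.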

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

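All tests of explanations in this part were chosen after the result was seen.

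Selection cassette rows, which no comparison used, were above the limit for 0 cells in ESC. The kanamycin row was detected in 70.1% (58.6% to 80%) of ESC, the puromycin row in 53.2% (41.5% to 64.7%) and the hygromycin B row in 35.1% (24.5% to 46.8%). All of these were found in 0 of 87 FL_HSC and 0 of 76 Eng_BM-HSC cells. In Eng_ES-HSC the kanamycin row was detected in 2 of 21 cells, the puromycin and hygromycin B rows in 0 of 21, which allows up to 14.3%. The YFP reporter row was detected in 3 of 21 and the eGFP row in 2 of 21 Eng_ES-HSC cells, each in 1 of 87 FL_HSC and in 0 of the ESC and Eng_BM-HSC cells. The labels do not name the constructs that any cells carried.

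Granulocyte, adult globin and T-cell transcripts appeared in cells labelled as engrafted ESC-derived HSC. The erythroid and T-cell parts were not particular to them. At least 3 erythroid genes were detected in 78.2% of FL_HSC and 47.6% of Eng_ES-HSC cells. At least 3 T and NK cell genes were detected in 44.2% of ESC, whose cells hold more detected genes, and 38.1% of Eng_ES-HSC cells. Fewer detected genes do not account for the granulocyte part: with 21 Eng_BM-HSC cells matched on gene number, 20 of them within 10%, the list median was still 1.93, above the central 95% of random lists, which ended at 0.58. One common pool of free RNA as the only source of both granulocyte and erythroid transcripts is argued against. In the 21 kept cells, scores from random splits of each list had a mean Spearman rho of 0.81 and 0.78 within the lists. Across the lists it was 0.013, a gap of 0.78 (bootstrap over cells 0.32 to 1.18). The gap was 0.65 (0.35 to 0.90) in all 47 cells. A pool that adds a low level of both to other sources could leave such a gap, so it stays open. An earlier test of S100a8, S100a9 and Hba-a2 used only the 22 of 47 cells that held all 3 genes, so its SD ratio of 1.37 (1.13 to 1.65 with any 1 cell left out) decides nothing. Mature blood cells among those labelled HSC remain a candidate source. In 8 cells at least 3 genes of both the granulocyte and HSC identity lists were held. Since 85.7% of ESC also pass for HSC identity, this decides nothing. Both the granulocyte and erythroid lists reached 3 genes in 8 of 21 Eng_ES-HSC cells. That held for 0 of 76 Eng_BM-HSC and 23 of 87 FL_HSC cells. Another 8 Eng_ES-HSC cells held the granulocyte list without the erythroid list, and 2 the reverse. Doublets were not called, so mixed cells cannot be told from single ones. Separate pools, library and a biological difference of ESC-derived cells also stay open, untested.

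HSC identity genes were lower in Eng_ES-HSC than in Eng_BM-HSC. Low gene number does not account for all of it, since the median with matched cells was -0.70, below the central 95% of random lists, which began at -0.14, although it had been -0.99 before matching. A library or preparation effect cannot be told apart from the group, as each group has 1 library identifier. A biological difference between ESC-derived and marrow HSC, and mature cells in the sample, stay open as hypotheses.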

How the results depend on the processing

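No paired analysis was possible because the groups share replicate numbers only as cell numbers in the titles, and no test was run. Results with cells of 1000 to 3000 genes, without cells over 50% mitochondrial, with near-identical cells counted separately or with matched gene number were chosen after seeing the data. The share of Eng_ES-HSC cells nearest to Eng_BM-HSC stayed at 100% under every alternative run for it. Most of these did not narrow the gap in gene number, in which Eng_BM-HSC was also the nearest reference. With cells of 1000 to 3000 genes, the reference means came from 65 Eng_BM-HSC, 18 FL_HSC and 6 ESC cells. The steady share therefore does not separate likeness from gene number or from the number of reference cells. Of 137 gene differences followed through 15 alternatives, 1 changed sign, Mt2. These genes had been named for the size of their differences in the same data, so sign changes were unlikely from the start. The filters on low genes leave the value of a gene as it was. The count is therefore no evidence of stability. Among gene differences 257 moved, 171 upward and 86 downward, while 1796 stayed the same. Of the lists that answer no comparison directly, 141 values moved, 94 upward and 47 downward, 26 changed sign and are given below, and 2248 stayed. A value that stayed could still shift by much, since the tolerance was the spread between single cells. With matched gene number, the class II median of Eng_ES-HSC minus Eng_BM-HSC went from -1.53 to -0.84. It counted as the same under its tolerance of 1.61. Shares of cells under other detection thresholds or no filter moved in 137 cases, 34 upward and 103 downward, and stayed in 271. Of the values that answer a comparison, 561 list medians, 68 correlations and 79 all-gene medians stayed the same. The spread between single cells, used as tolerance here, was larger than some of the medians themselves, so staying the same says little for them. For Notch genes in Eng_ES-HSC minus Eng_BM-HSC the tolerance was 0.51, against a median of -0.12. Trimmed means, leaving out cells over 50% mitochondrial, and counting near-identical cells separately moved none of the values that answer a comparison. The cause of the shifts below was not tested, apart from pseudocounts and gene filters, which rescale values or change the genes used. The small number of Eng_ES-HSC cells limits shares near 0: 21 cells allow detection in up to 14.3% for a gene seen in 0. Below, ES, BM and FL stand for Eng_ES-HSC, Eng_BM-HSC and FL_HSC, and a hyphen stands for minus.

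At a pseudocount of 0.1, HSC identity genes gave -1.85 (ES-BM), -4.80 (ES-FL), 4.91 (FL-ESC) and 1.85 (BM-ESC). Fetal HSC program genes gave -2.73 (ES-FL), -2.79 (BM-FL), -1.86 (ES-ESC) and -1.78 (BM-ESC). The median over all genes gave -1.47 (ES-ESC) and -1.19 (BM-ESC). Pluripotency genes gave -7.05 (ES-ESC), -6.98 (FL-ESC) and -6.83 (BM-ESC). With the pseudocount at 10, HSC identity genes gave -1.37 (ES-FL) and 1.38 (FL-ESC). Fetal HSC program genes gave -0.72 (ES-FL) and -0.62 (BM-FL). Pluripotency genes gave -1.96 (ES-ESC), -1.94 (FL-ESC) and -1.96 (BM-ESC). Keeping low genes, the profile correlation gave 0.797 (ES/BM), 0.753 (ES/FL), 0.879 (BM/FL), 0.703 (ES/ESC), 0.813 (FL/ESC) and 0.791 (BM/ESC). The median over all genes gave -0.10 (ES-ESC). For genes with a mean TPM of 10 or more, Notch pathway genes gave -0.68 (ES-BM), -1.24 (ES-FL) and 0.24 (BM-ESC). The profile correlation gave 0.541 (ES/FL), 0.461 (ES/ESC) and 0.491 (BM/ESC). The median over all genes gave -1.07 (ES-FL), -1.29 (ES-ESC) and -1.03 (BM-ESC). Hoxa cluster genes gave -1.31 (ES-FL), 1.15 (FL-ESC) and 0.52 (BM-ESC). Early lymphoid genes gave 0.48 (ES-ESC). Without a filter on cells, MHC class I genes gave -0.15 (ES-FL). When cells needed 2000 genes, oxidative phosphorylation genes gave 1.01 (ES-BM). MHC class II genes gave -0.016 (ES-ESC). Taking log2 of the mean TPM, the profile correlation gave 0.579 (ES/BM), 0.430 (ES/ESC) and 0.523 (BM/ESC). The median over all genes gave -0.67 (ES-BM) and -1.13 (ES-FL). HSC identity genes gave -4.21 (ES-BM), -4.41 (ES-FL), -0.16 (BM-FL), 4.94 (FL-ESC) and 4.59 (BM-ESC). Early lymphoid genes gave -1.44 (ES-BM), -1.56 (ES-FL), 0.88 (BM-FL), 1.87 (FL-ESC) and 3.15 (BM-ESC). Hoxa cluster genes gave -1.44 (ES-BM), -2.41 (ES-FL), 1.97 (FL-ESC) and 1.44 (BM-ESC). Fetal HSC program genes gave -3.50 (ES-FL). Immediate early genes gave 0.83 (ES-FL) and 0.38 (BM-FL). Quiescence genes gave 0.83 (BM-FL). Pluripotency genes gave -5.70 (ES-ESC), -5.83 (FL-ESC) and -5.95 (BM-ESC). Notch pathway genes gave 0.79 (FL-ESC). Hoxb cluster genes gave 0.87 (FL-ESC) and 1.14 (BM-ESC). Mt2 gave 0.47 (ES-ESC). After quantile normalization, immediate early genes gave 0.11 (BM-FL). HSC identity genes gave 1.81 (BM-ESC). Without mitochondrial, ribosomal and globin genes, pluripotency genes gave -5.29 (FL-ESC). Among odd-numbered cells, the profile correlation gave 0.615 (ES/BM), 0.533 (ES/FL) and 0.475 (ES/ESC). Among even-numbered cells, the profile correlation gave 0.489 (ES/ESC). In cells with 1000 to 3000 genes, the profile correlation gave 0.575 (ES/BM), 0.402 (ES/FL), 0.590 (BM/FL), 0.418 (ES/ESC), 0.390 (FL/ESC) and 0.442 (BM/ESC). HSC identity genes gave -1.06 (ES-FL), -0.064 (BM-FL), 1.52 (FL-ESC) and 1.59 (BM-ESC). Notch pathway genes gave 0.057 (ES-FL), 0.43 (BM-FL), 0.26 (ES-ESC) and 0.59 (BM-ESC). Fetal HSC program genes gave -0.80 (ES-FL), -0.53 (BM-FL), 0 (ES-ESC) and 0.38 (BM-ESC). Immediate early genes gave 0.11 (ES-FL) and 0.79 (BM-FL). Homing and adhesion genes gave 0.080 (ES-FL). The median over all genes gave 0.16 (BM-FL), 0 (ES-ESC) and 0.27 (BM-ESC). Early lymphoid genes gave 0.76 (BM-FL). Quiescence genes gave 0.36 (BM-FL). Endothelial genes gave 0.46 (BM-FL). Oxidative phosphorylation genes gave 0.23 (BM-FL), 0.14 (ES-ESC) and 0.50 (BM-ESC). Housekeeping genes gave 0.64 (BM-FL) and 0.18 (ES-ESC). Pluripotency genes gave -1.60 (ES-ESC), -1.64 (FL-ESC) and -1.59 (BM-ESC). S phase genes gave 0.026 (ES-ESC) and 0.87 (FL-ESC). Glycolysis genes gave 0.11 (ES-ESC) and 0.41 (BM-ESC). G2 and M phase genes gave 0.62 (FL-ESC). Chromatin regulators genes gave 0.36 (FL-ESC) and 0.080 (BM-ESC). Imprinted genes gave 0.17 (BM-ESC). With Eng_BM-HSC cells matched on gene number, oxidative phosphorylation genes gave 0.60 (ES-BM).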

Other observations

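Of the tests in this part, the joint test of Ebf1 and Fam73a was fixed before its result was seen, though its rule was changed afterwards. The tests of each gene alone and the comparisons with matched gene number were chosen afterwards. Most p53 target genes were lower in the HSC groups than in ESC. Of 13 measured p53 targets, 9 were lower by at least 1 in Eng_ES-HSC and in FL_HSC than in ESC and 10 in Eng_BM-HSC, with medians of -1.85, -1.78 and -1.77. These lay at the 3.84th percentile for Eng_ES-HSC, inside the central 95% of random lists, and at the 0th and 0.66th for FL_HSC and Eng_BM-HSC. Cdkn1a, a cyclin-dependent kinase inhibitor, was detected in 90.9% of ESC and 14.9% of FL_HSC. Immediate early genes had medians of 1.10, 1.38 and 1.10 relative to ESC in Eng_ES-HSC, FL_HSC and Eng_BM-HSC. Between HSC groups, Egr1, an early response factor linked to HSC quiescence, was detected in 88.2% of Eng_BM-HSC, 56.3% of FL_HSC and 23.8% of Eng_ES-HSC cells. The heat shock genes Hspa1a and Hspa1b were found in 33.3% and 38.1% of Eng_ES-HSC cells and listed at 0 in every Eng_BM-HSC cell. Quiescence genes had a median of -0.56 in Eng_ES-HSC minus Eng_BM-HSC at the 10.7th percentile, and of -0.16 with matched gene number.

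The imprinted genes Igf2 and Grb10 were detected mostly in FL_HSC among the HSC groups, while between HSC groups imprinted genes as a list lay inside the range of random lists. Igf2, a fetal growth factor, was detected in 28.7% of FL_HSC and 0% of both engrafted groups, and Grb10 in 77% of FL_HSC, 14.5% of Eng_BM-HSC and 0% of Eng_ES-HSC cells. Megakaryocyte genes had a median of -1.01 in Eng_ES-HSC minus FL_HSC, and Gp9, a platelet glycoprotein, was found in 64.4% of FL_HSC cells. Chromatin regulators (-1.56), cytokine receptors (-0.33), homing genes (-1.10) and endothelial genes (-0.997) lay inside the central 95% of random lists there. Markers of liver and stroma were near 0, at -0.070 and -0.091, and Alb was listed at 0 in every HSC. Imprinted genes had a median of -0.58 at the 13.8th percentile there, and of -1.10 at the 0.44th percentile in Eng_ES-HSC minus ESC. In Eng_ES-HSC minus FL_HSC, embryonic globin had a median of -0.15. The X-inactivation and Y-linked list had a median of -0.48 there, over 4 measured genes that were all Y-linked, since Xist was not analysed. Relative to ESC, germ layer genes had a median of -0.64 and the 1 measured Cdx factor -0.28 in Eng_ES-HSC. Between the engrafted groups the medians were 0 for B-cell genes, -0.82 for class I genes and -0.42 for interferon response genes. With matched gene number the class I median was -0.20, and the interferon response median -0.33 at the 1.21st percentile, below the central 95% of random lists, where it had been inside at the 4.42nd. Embryonic globin Hbb-y was detected in 3.45% of FL_HSC cells only.

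Ebf1 and Fam73a were detected in all 21 kept Eng_ES-HSC cells, and a fixed amount of background signal per cell may give such values. Before the cell filter Ebf1 was in 47 of 47 cells and Fam73a in 37 of 47. The test fixed in advance was the median Spearman rho with gene number over both genes in the other 3 groups. It gave 0.12, which by its fixed rule counted against background for both genes together. Since the genes went opposite ways, every rho was then required to pass the bound, after the result had been seen. Under that changed rule the test decides nothing. Split by gene afterwards, Fam73a had a median rho of 0.55 and was positive in every group, which argues against background. Ebf1 had a median of -0.33, from -0.53 in Eng_BM-HSC to -0.074 in FL_HSC, and -0.60 in Eng_ES-HSC itself. The share of widely detected genes below -0.3 was 16.9% in Eng_ES-HSC, 2.4% in Eng_BM-HSC, 0.39% in ESC and 0.29% in FL_HSC. With FL_HSC near 0, Ebf1 stays open.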
